A study of Homo sapiens with 11 samples.

How the data were processed

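Skin punch biopsies of patients with juvenile systemic sclerosis and of healthy controls were measured by single-cell RNA sequencing. Per the labels' protocols, 7 patient and 2 healthy samples were dissociated with an enzyme kit for whole skin and made into 10x Genomics 3′ libraries that are labelled V2, and 2 patient samples were taken from FFPE sections and measured with the probe-based Flex assay. Samples were grouped by the disease state in the labels and by this difference in protocol. The labels do not pair samples. The submitters' processing notes name Cell Ranger and Seurat and the build GRCh38 for all samples and SAMtools for the FFPE samples, without versions. The reference annotation, the cell-calling settings and the way libraries were joined are not given in the sources used here.

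The tables analysed were deposited by the authors for the series as a whole. One lists 65092 cell barcodes, each with a library index after a hyphen, and the other lists 33538 genes by Ensembl identifier and symbol, all of the gene expression type. Neither holds a measured value, so no unit, normalisation or depth in reads applies, and the depth of each library is known only as its number of cell barcodes (615 to 8685). The names of the deposited tables call the matrix filtered, and what the filter removed could not be tested on them. Whether it holds the FFPE samples is not given in the sources used here. The counts of transcripts were not analysed here. The planned tests between patients and controls, of barcodes per library and of genes per cell type, were therefore not run, the first because no index matched the label of a single sample and the second because it also needs counts. Cells were not clustered, and doublets were not assessed. Columns of per-sample values that were left out numbered 0.

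Barcodes were split into sequence and index. Shares of cells have exact Clopper-Pearson intervals and numbers of shared sequences have exact Poisson intervals, both at a level of 95%. They cover counting error only. Indices were linked into sets if their barcodes had equal length and the frequencies of their first 4 bases correlated above 0.4. The sets were thus defined without the sharing of whole sequences, but from the first bases of the same barcodes. Indices with unlike first bases can share fewer whole sequences, so sharing is not independent of the sets. This split was chosen after the data were seen. Base composition was counted per position. The size of a barcode pool was estimated by capture and recapture, as the sum over pairs of indices of the product of their numbers of barcodes, divided by the number of sequences they shared. Uneven draws from a pool lower this estimate. Each pair of sets 1 and 2 was compared with the number expected from the other pairs of its set, by a two-sided exact Poisson test that takes the expected number as known, with Benjamini-Hochberg adjustment over the 43 pairs. On simulated libraries of the same sizes drawn from pools of known size, all libraries were placed in their own set in 20 of 20 draws. Each made pool was given its own frequencies of the first 4 bases, so this placement was built in. Whether a single pool would be split falsely was not checked. The interval held the true pool in 20 of 20 draws for sets 1 and 2 and in 19 of 20 for set 3. These draws were even, so the intervals were not checked under uneven draws.

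Gene identifiers were matched without their version to GENCODE 29 (GRCh38), which held 33456 of them, and 33071 had the same symbol there. It may not be the release the authors used. Coordinates are those of GENCODE 29, counted from 1. Gene lists for cell types and pathways were fixed before the data were examined, and matched by current symbol or, through the identifier, by older symbol. The rule for the genes to be named, with no expression values, was every member of the lists that the table lacked or listed more than once, and the 5 symbols with the most rows. Genes with shared sequence fall outside that rule and were chosen after their values were seen. For each fixed-list gene, the words of 60 bases in the last 300 bases of its transcripts of the gene's own type (protein-coding ones for a protein-coding gene) were searched in all transcripts of the other listed genes, and the exons of all its transcripts were intersected with those of other listed genes on the same strand. Read length and the treatment of reads that match several genes are not given in the sources used here. On 40 made genes, 10 of them with a copied end, the word search returned the number of shared words put in for 40 of 40.

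The alternatives fixed before the data were examined were leaving out sequences found under more than 1 index, leaving out each index, allowing 1 mismatch, other estimates of the pool, counting each distinct sequence or symbol once, and matching by older symbols. Alternatives for the sets, the pair of indices 2 and 3 and the word search were added afterwards. Analyses used Python 3.11.15, NumPy 2.4.6 and SciPy 1.17.1, and plots used Matplotlib 3.10.9.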

Results

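The series addressed macrophage and fibroblast signalling in the skin in juvenile systemic sclerosis, an autoimmune disease with fibrosis of the skin and internal organs, by single-cell RNA sequencing of skin punch biopsies. The labels give 11 samples in 3 groups. In 7 samples from patients and 2 samples from healthy controls, cells were released from the biopsy by enzymatic dissociation and sequenced with a droplet-based 3′ assay, which reads the end of each transcript next to its poly(A) tail. In 2 further patient samples, cells came from sections of formalin-fixed, paraffin-embedded (FFPE) tissue and were measured with hybridised probes. The data described here are the gene list and the cell barcode list of 1 filtered matrix that pools libraries. The counts of transcripts per gene and cell were not analysed here, so the report gives no expression level, no cell type and no difference between patients and controls. It describes which genes the list holds, which of them share sequence, and how the cells were spread over libraries.

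All of the cell type markers and pathway genes chosen before the data were examined were in the gene list, which does not show that their transcripts were detected. The 21 lists held 301 entries and 284 distinct genes, of which 17 stood in more than 1 list. The gene list held 280 of the 284 genes under their current symbols and the other 4 under older symbols, so that 0 of the 284 genes were missing. The list covered 33538 genes, all of the gene expression type and each with its own Ensembl identifier. By the GENCODE 29 annotation (GRCh38), 19880 of them, or 59.3%, were protein-coding genes and 12917, or 38.5%, were long non-coding RNA genes. That annotation has 19951 protein-coding genes, so the list held nearly all of them. Almost any list of protein-coding genes would thus be complete, and the complete lists given below are no finding about these samples. A further 645 were immunoglobulin or T cell receptor gene segments, pseudogenes of these included. The 13 mitochondrial genes listed were the 13 protein-coding genes of the mitochondrial chromosome that served as RNA quality markers. Of small RNA, ribosomal RNA and mitochondrial structural RNA genes, 0 were listed. The annotation lacked 82 of the identifiers, which were left out of these counts by type.

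The fibroblast list was complete, with 25 of 25 genes listed. It includes COL1A1 and COL1A2, which encode the chains of type I collagen, PI16 and CD34, which mark stem-like adventitial fibroblasts, and SFRP2, SFRP4, COMP and POSTN, which are known from fibroblasts that deposit matrix. The macrophage list was also complete, with 20 of 20 genes. It includes the scavenger receptors CD163 and MARCO, the complement genes C1QA, C1QB and C1QC, the monocyte genes FCN1, S100A8 and S100A9, and SPP1, which encodes osteopontin. Of the genes for signals and receptors that could pass between macrophages and fibroblasts, 66 of 66 were listed, among them TGFB1 and its receptors TGFBR1 and TGFBR2, CSF1 and its receptor CSF1R, and MIF and its receptor CD74. The interferon response list (22 of 22 genes, such as ISG15, MX1 and CXCL10) and the list of genes whose products are autoantigens in systemic sclerosis (13 of 13 genes, such as TOP1, CENPB and POLR3A) were complete. Complete lists were also found for dendritic cells (9 genes), T cells (9 genes), NK cells (5 genes), B and plasma cells (7 genes), mast cells (6 genes) and vascular endothelium (8 genes). The same held for lymphatic endothelium (6 genes), pericytes and smooth muscle (9 genes), melanocytes (6 genes), Schwann cells (7 genes), sweat and sebaceous glands (8 genes) and erythroid cells (4 genes). The list of dissociation stress genes (14 genes, such as FOS, JUN and HSPA1A) was complete as well.

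The matrix and TGF-β response list had 28 of 31 genes under their current symbols, and the missing symbols were those of 3 matricellular growth regulators. CCN2, the connective tissue growth factor, was listed as CTGF (ENSG00000118523, chromosome 6, 131948176 to 131951373, minus strand). CCN1 was listed as CYR61 (ENSG00000142871, chromosome 1, 85580761 to 85583962, plus strand). CCN3 was listed as NOV (ENSG00000136999, chromosome 8, 119416306 to 119424353, plus strand). The keratinocyte list had 12 of 13 genes under current symbols, and LORICRIN, a protein of the cornified envelope of the epidermis, was listed as LOR (ENSG00000203782, chromosome 1, 153259700 to 153262122, plus strand). All 4 are protein-coding genes.

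RGS5, a marker of pericytes, was the only gene of the fixed lists whose symbol named 2 features. The protein-coding gene (ENSG00000143248, chromosome 1, 163111121 to 163321791) and a non-coding gene (ENSG00000232995, chromosome 1, 163244505 to 163321894) lie on the minus strand and overlap. They shared 534 of the 6821 exon bases of the coding gene, or 7.83%. In the whole list, 24 symbols stood in 2 rows each and none in more. In alphabetical order, the first 5 of these symbols, which tie for the number of rows, were ABCF2, ATXN7, CCDC39, COG8 and CYB561D2.

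Sequence shared with another listed gene was then measured, because a 3′ read that matches several genes cannot be given to any of them by sequence alone. The genes named in this paragraph and the next were chosen after their values were seen. MIF, the macrophage migration inhibitory factor, had the highest share of the 284 genes in the last 300 bases. Of the 241 different words of 60 bases in the last 300 bases of its transcript, 238, or 98.8%, also occurred in AP000350.4, a protein-coding gene of the same strand. MIF (ENSG00000240972) lies on chromosome 22 from 23894004 to 23895227, and AP000350.4 (ENSG00000251357) spans 23862188 to 23895223. Their exons had 357 bases in common, which is 32.2% of the 1109 exon bases of MIF, in the intervals 23894772 to 23894944 and 23895040 to 23895223. The genes for α-globin, carried by red blood cells, shared 64.2% of the 3′ end words of HBA2 and 59.8% of those of HBA1 with each other. IGHG1, the constant region of immunoglobulin G1 and a plasma cell marker, shared 54.9% of its 3′ end words with IGHG2. These 4 genes were the only ones of the 284 with 50% or more of the 3′ end shared by this measure. The measure counts the different words of all transcript ends of a gene, so many unlike ends lower the share. With words of 90 bases IGHG1 fell to 42.8%, and over the last 500 bases the mast cell tryptase gene TPSAB1 reached 52.4%, while MIF, HBA1 and HBA2 were at 50% or more in all 3 settings. Over the last 500 bases the order changed, with 80.4% for HBA1, 73.0% for HBA2 and 68.3% for MIF.

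**Figure D1:**
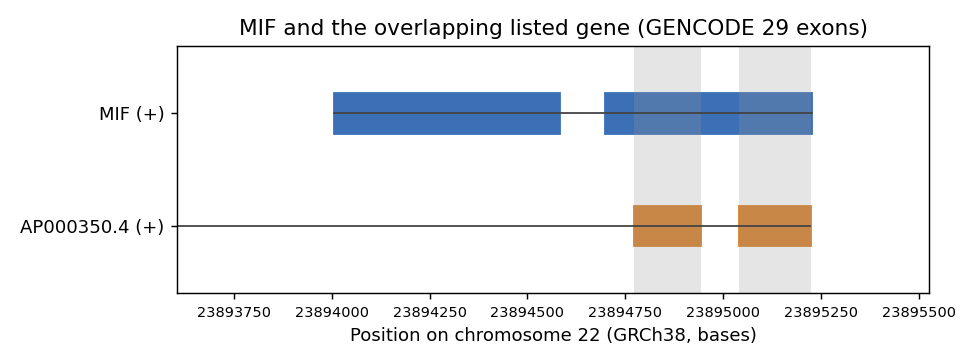
Exons of MIF (blue) and AP000350.4 (orange) along chromosome 22 in GRCh38, as the union over GENCODE 29 transcripts, with position in bases on the horizontal axis and thin lines for introns. The grey bands mark the 357 exon bases present in both genes, which lie in the last exon block of MIF.

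Smaller shares were found for genes of several lists. The keratinocyte list had 3 of 13 genes with shared words, DSC1 at 8.30%, KRT5 at 5.42% and KRT16 at 2.90%. The mast cell tryptases TPSAB1 and TPSB2 shared 26.5% and 30.6% of their 3′ end words with each other. CD8B, a co-receptor chain of cytotoxic T cells, shared 26.7% with CD8B2, and FCGR3A, an Fc receptor of macrophages and NK cells, shared 19.8% with FCGR3B. LGALS9, which encodes the ligand galectin 9, shared 18.2% with other listed genes, mostly LGALS9C. RNPC3, an autoantigen gene, shared 17.2% with AMY2B. Some of these shares are low because the transcripts have many different ends, not because few words were shared. RNPC3 shared 239 of 1389 words, CD8B 230 of 862 and LGALS9 214 of 1176, against 238 of 241 for MIF. Several of these shares depended on the word length. With words of 90 bases, FCGR3A fell to 0.274%, LGALS9 to 5.05%, CD8B to 15.8%, TPSAB1 to 17.3%, TPSB2 to 20.3% and KRT5 to 3.64%, DSC1 and KRT16 shared 0 words, and RNPC3 was at 16.6%. Over the last 500 bases, TPSB2 was at 48.4%, LGALS9 at 26.4% and FCGR3A at 24.7%. In that setting SELE, an adhesion molecule of endothelium, was at 15.5%, against 0.692% in the last 300 bases, and HSPA1A was at 20.4%, against 0%. In all, 18 of the 284 genes shared at least 1 word, which leaves 266 that shared none. The number was 11 with words of 90 bases and 26 over the last 500 bases. None of the fibroblast markers COL1A1, COL3A1, LUM and PDGFRA was among the 18, while DCN shared 0.0659% of its words. By exon position, 18 genes overlapped another listed gene of the same strand, and 4 of these also shared words at the 3′ end. The 18 genes with overlapping exons were 6.34% of the 284 genes (95% Clopper-Pearson interval 3.80 to 9.83), against 12.4% (11.9 to 12.8) of the 19880 listed protein-coding genes. ITGB3, an integrin chain, overlapped AC068234.1 over 51.6% of its exon bases but shared 0 of its 482 3′ end words in the last 300 bases and 5.33% over the last 500. PDGFRA, the receptor of platelet-derived growth factor in fibroblasts, overlapped AC058822.1 over 15.8% of its exon bases and shared none of its 3′ end words in either setting.

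The cell barcode list held 65092 cells under 16 library indices, the number that follows each barcode. No index matched the label of a single sample, so the indices stand here for unmapped libraries, and 7 of them exceed the 9 dissociated samples of the labels. The median was 4254.5 cells per index. Index 5 held the most, with 8685 cells or 13.3% of all cells (95% Clopper-Pearson interval 13.1 to 13.6). Index 6 held the fewest, with 615 cells or 0.945% (0.872 to 1.02), so that the range was 14.1-fold. The next fewest, 2087 cells, were under index 16, so the lower end of the range rests on index 6 alone. These intervals cover counting error only. No barcode was repeated within an index. Of all barcode bases, 50.2% were G or C (50.1 to 50.3). The share of a single base at a single position ranged from 20.9% to 32.5% in the 2 indices with barcodes of 14 bases. In barcodes of 16 bases it ranged from 23.1% to 26.9%, but over wider ranges within the sets of indices described next, 23.0% to 28.1% in set 1 and 21.9% to 30.5% in set 2.

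**Figure D2:**
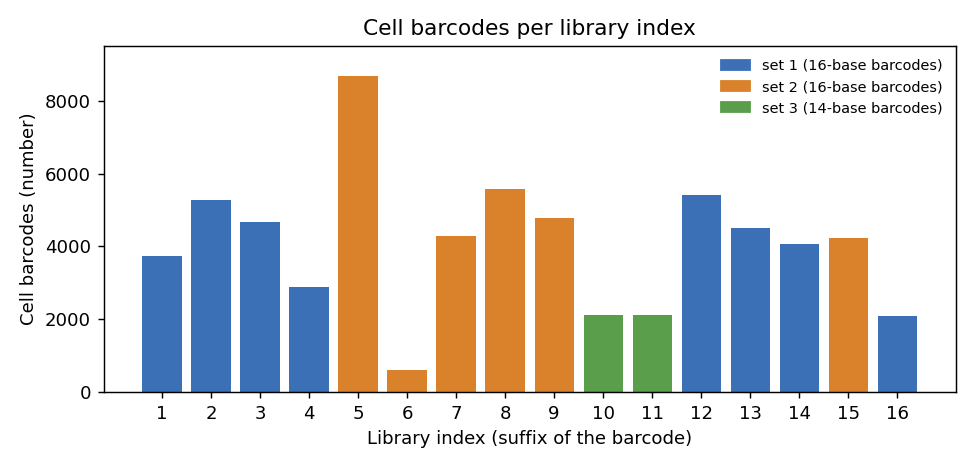
Number of cell barcodes (vertical axis) for each of the 16 library indices (horizontal axis), with bars coloured by the set of indices that share a barcode length and composition. Index 5 has 8685 barcodes and index 6 has 615, while indices 10 and 11, with 14-base barcodes, have 2126 and 2109.

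The indices fell into 3 sets by the length and the first 4 bases of their barcodes, while the first 3 bases gave 2 sets, with sets 1 and 2 joined. Indices 10 and 11 had barcodes of 14 bases (set 3), and all others had barcodes of 16 bases. Among these, the frequencies of the first 4 bases separated indices 1 to 4, 12 to 14 and 16 (set 1) from indices 5 to 9 and 15 (set 2). Across the 256 possible 4-base words, correlations between indices were 0.56 to 0.94 within sets and 0.02 to 0.20 across sets. These correlations are across words, which are not independent replicates. Set 1 held 32685 cells (50.2% of all), set 2 held 28172 (43.3%) and set 3 held 4235 (6.51%). The medians were 4289, 4534 and 2117.5 cells per index. The sets were defined from the barcodes alone, and how they relate to the groups of the study was not tested, since no index matches a sample.

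Identical barcode sequences in different libraries give the size of the barcode pool from which the libraries drew. Within set 1, 157 sequences were shared over 28 pairs of indices, which puts the pool at 2947468 barcodes (exact 95% Poisson interval 2520858 to 3468853). Without the pair of indices 2 and 3, taken up below, the estimate was 3369826. Within set 2, 410 sequences were shared over 15 pairs, which puts the pool at 765420 (694799 to 845268). The only pair of set 3 shared 6 sequences, for a pool of 747289 (343332 to 2036308). The intervals of sets 1 and 2 did not overlap. Between sets 1 and 2, 22 sequences were shared over 48 pairs, where 312 would be shared if all of these indices drew on the pool of set 1. The labels give a pool of about 737000 barcodes for the FFPE probe assay. That number lies within the intervals of sets 2 and 3 and outside that of set 1. A match in size does not show which assay an index came from, and the pools of other assays were not compared. The wide interval of set 3 rests on 6 sequences. Barcodes of 14 and of 16 bases cannot be identical, so sharing between set 3 and the other sets was not tested. Over all 120 pairs of the 16 indices the planned estimate was 3293428 (3039118 to 3574944). It includes pairs across sets, which shared few or no sequences and raise it, so neither the value nor its interval describes a pool.

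**Figure D3:**
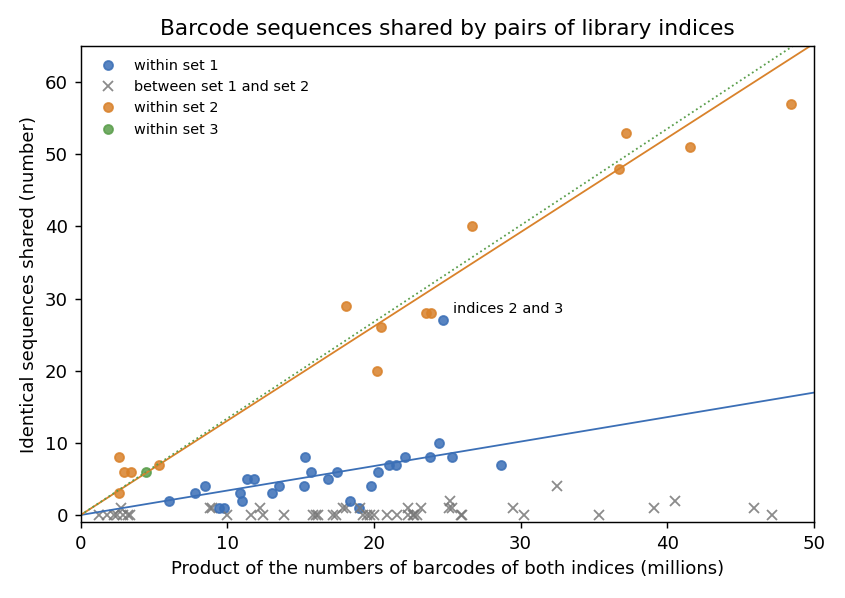
Identical barcode sequences shared by each pair of library indices with equal barcode length (vertical axis, number) against the product of their numbers of barcodes (horizontal axis, in barcode pairs, scaled as its label states). Lines give the number expected from the pool estimate of each set, and the pair of indices 2 and 3 lies above the line of set 1.

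One pair of libraries shared more sequences than the others of its set. Indices 2 and 3 had 27 sequences in common, against 7.32 expected from the other pairs of set 1, a ratio of 3.69 (95% interval 2.43 to 5.36). In exact two-sided Poisson tests of the 43 pairs of sets 1 and 2 this was the only pair with a Benjamini-Hochberg adjusted p under 0.05 (adjusted p = 1.56e-06). An unadjusted p under 0.05 was found for 3 pairs. Besides indices 2 and 3 these were indices 3 and 14, with 1 sequence against 6.68 expected, and indices 6 and 15, with 8 against 3.36 expected. The numbers expected for the other pairs of set 1 include the pair of indices 2 and 3, which raises them. The lowest adjusted p of the other pairs was 0.413.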

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

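Of 76 alternative values, 65 kept the result, a tally that does not measure robustness. Counts and medians kept it within a wide fold band, and pools and base composition within the 95% interval. Sets had to keep the same indices, and indices 2 and 3 a p below the threshold. Several values could hardly move. The median was 4228 or 4281 cells with any 1 index left out, against 4254.5. For set 3, the estimate from the number of distinct sequences equals the first one. The planned pool estimate over all 16 indices moved most. It was 3293428 barcodes, 3007261 to 3993735 when each index was left out in turn, and 42517418 as the median of the pairs' own estimates. It rose without any index of set 2 and fell without any other index. The alternatives for the separate sets, chosen after the data were seen, stayed within the 95% interval of each estimate, and without the pair of indices 2 and 3 the pool of set 1 was 3369826. Words of 3 bases in place of 4 joined sets 1 and 2, for 2 sets instead of 3, and the cause was not tested. The other 4 alternatives for the sets put the same indices in each. The fixed-list genes that shared any 3′ end word numbered 18, against 11 with words of 90 bases. The ratio for indices 2 and 3 was 3.46 to 3.97. Allowing 1 mismatch added no shared sequence, so it tests nothing. Settings fixed in advance for the comparison of patients with controls were not run: the log2 scale of barcodes per library, leaving out each library, DESeq2, no filter on low counts, and adding the FFPE libraries. No paired analysis was possible because the indices match no sample. With 6 shared sequences, the pool of set 3 is limited to a range from 343332 to 2036308.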

Other observations

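All tests in this part were chosen after the result was seen, except the search for the sequences of indices 2 and 3 under further indices, which was written down before its result was seen.

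MIF encodes a secreted cytokine whose receptor is CD74, and both were on the list of signals between macrophages and fibroblasts. In this gene list, 98.8% of the 3′ end words of MIF also belong to AP000350.4, whose exons overlap those of MIF on the same strand. How reads from these bases were counted was not tested, as this needs the counts of both genes. TGFB1, CSF1, CSF1R, CD74 and SPP1 each shared 0 of their 3′ end words with another listed gene.

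Sets 1 and 2 of the library indices shared few barcodes with each other, and set 3 has barcodes of another length. A single, evenly drawn pool sampled to different depth is argued against by the 22 sequences shared between sets 1 and 2, which are 0.0704 of the number expected from the larger pool (95% interval 0.0441 to 0.107, with the expected number taken as known). Draws that are uneven in the same way in all libraries would raise sharing between sets as much as within them. At the rate of sharing within set 1, 312 sequences would be shared between sets 1 and 2, and at that within set 2, 1203. The 22 found therefore argue against such draws as well. Uneven draws that differ between the sets stay open. The matrix joins barcodes of 14 bases (set 3) and of 16 bases (sets 1 and 2). A list of barcodes of a single length therefore cannot have served all indices. A hypothesis is that the matrix may join libraries of more than 1 chemistry, while the labels give V2 for all 9 dissociated samples. Comparing the barcodes with the list of each chemistry, not used here, or a map from index to library would decide it. The split of sets 1 and 2 is lost with words of 3 bases, which gave 2 sets. Set 2 has 6 indices, so if the 9 labelled libraries are among the 16 indices, at least 3 of them lie outside set 2, and whether the sets follow disease state stays open because the indices match no sample.

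The design text adds further healthy samples, for 9 patients and 9 controls in all. These 18 less the 2 FFPE samples equal the number of indices, 16, which does not show what any index is.

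Indices 2 and 3 shared 27 sequences where 7.32 were expected. Chance is argued against by the adjusted exact Poisson p of 1.56e-06 over 43 pairs, and the same cells sequenced as a pair of libraries by the share of 0.578% of the sequences of index 3 (95% Clopper-Pearson interval 0.382 to 0.840). Barcodes drawn more often in every library of set 1 would raise sharing in all pairs, and the expected number comes from the other pairs. The other pairs of index 2 or 3 had ratios of 0.15 (indices 3 and 14) to 1.57 (indices 2 and 4), against 3.69 here. Their expected numbers include the pair of indices 2 and 3, which lowers their ratios somewhat. With the pool taken from pairs with neither index, the ratio of indices 2 and 3 was 3.46. These values argue against such barcodes as the cause of the excess in this pair. Of the 27 sequences, 1 was found under a further index of set 1, or 3.70% (0.0937 to 19.0). The share was 0.616% for the 9900 other sequences of both indices, so the interval is too wide for this search to decide by itself. Reads carried from one library into the other were not tested, as this needs reads per barcode, and no biological explanation was tested.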
